A study of Rattus norvegicus with 12 samples.

How the data were processed

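RNA from the thoracic spinal cord of rats was measured on 12 Illumina rat expression arrays, each with 1 pool of RNA, for 2 genotypes in 6 conditions of surgery and time. The pools were assigned to conditions from the labels. Per the labels' protocols, RNA was pooled before labelling and its quality was checked on a bioanalyser.

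The deposited intensity values are bead-average signals read with BeadStudio 3.2.6, per the submitters' processing notes. They are background-subtracted, since 21.0% to 28.6% of the values of an array lie below 0. The means of the arrays lay between 324.9 and 326.9, so that an earlier scaling to a common mean is not excluded. A detection p-value per probe and array is deposited beside each signal, per the file headers. A second table deposited by the authors, the series matrix, holds intensity values that are a straight line of the signals on each array, with slopes between 0.289 and 0.42 and intercepts between 0 and 9.26. They are linear and not centred, with array medians between 6.27 and 11.71, and the kind of normalization is not given in the sources used here.

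The deposited probe identifiers appear to stand beside the values of other probes. The values follow the sorted order of the identifiers while the identifier column does not, and the series matrix carries the same pairing. Identifiers were therefore sorted before they were joined to the values. Receptors of smell served as genes expected to be silent in the cord and ribosomal and proteasome genes as genes expected to be active. The z score of their difference in mean log2 signal was 0.322 as deposited and 26.1 after sorting, against at most 4.36 over the 22225 other shifts of the sorted column. In each of 10 equal stretches of the file, at most 9.66% of the first and at least 79.8% of the second were detected. This pairing was inferred from the data and is not stated by the authors. Of 22226 probes, 13192 had 1 gene symbol, 9034 had none and 0 had several.

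Signals were normalized with neqc of limma 3.58.1 in R 4.3.3, which models the background from the detection p-values, adds an offset of 16 and applies quantile normalization. Probes were kept when their detection p-value was under 0.05 on at least 2 of the 12 arrays, which left 13793 probes, 9423 of them named. One limma fit held the 6 conditions and the genotype, with eBayes and an intensity trend and 5 residual degrees of freedom, or 4 for the interaction. With 1 pool per condition, the residual is the change of the genotype difference between conditions, and a condition left with 1 pool is assumed to vary like the others. For genotype and the interaction, a condition left with 1 pool adds no comparison. Leaving out either pool of a pair is then nearly the same as leaving out the pair, and cannot point to 1 of its pools. Injury at 30 min and 4 h was compared with the sham pools of that time, and at 24 h and 7 d with the mean of all sham pools. P-values were adjusted by Benjamini and Hochberg within each of the 7 contrasts at a threshold of 0.05.

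The 37 gene lists were tested with camera at a preset correlation of 0.01, adjusted over 259 pairs of list and contrast, and again with an estimated correlation. Of 84 calls at the preset correlation, 0 held with the estimated one, where 40 pairs had an unadjusted p under 0.05. With an estimated correlation camera also uses the few residual degrees of freedom, so that a lost call cannot be put on correlation alone. For genotype, the hypoxia and glycolysis list had an estimated correlation of -0.0175, below the preset one. Its unadjusted camera p still moved from 0.0924 to 0.134. A gene was represented by its probe of highest mean signal, and 552 of the 698 list entries were on the array, 9 of them through a synonym. List means were compared between genotypes over 6 pairs with an exact sign-flip permutation test of 64 flips. List medians of single pools were placed among 10000 random lists of like size and expression.

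Named genes followed a rule. It took the 10 largest increases and the 10 largest decreases among named probes past the threshold with both genotypes in the same direction, or the 5 smallest p where none passed. It also took up to 4 members of each list described, and Sod1 always. The contrasts, lists, naming rule and most alternatives were chosen before the data were examined. The pairing of identifiers, the comparison of 7 d with 24 h, the genotype comparison at late times and the slopes of the late response over the settings were added afterwards. Leaving out each pool in turn was planned, but the genotype lists and the late genotype comparison without the wild-type 30 min injury pool were singled out afterwards. Lists in the added comparisons were adjusted over the 37 lists of each comparison.

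The fit was tested on simulated data with 13793 probes. Noise was independent between probes and pools, and many randomly drawn probes were changed at once, so that the shares below are no estimate of power in the real pools. Changes of 1 on the log2 scale were recovered in 94.0% of cases for genotype, 72.0% for injury at 4 h, 88.0% for injury at 24 h and 56.0% for the interaction. False calls were 4 of 179, 7 of 165, 6 of 175 and 3 of 146. Alternatives varied background correction, normalization, the detection filter, the eBayes settings, the design terms, the sham reference and the pools included. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.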

Results

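Gene expression was measured in the thoracic spinal cord of female Sprague-Dawley rats aged 10 weeks, after a mild compression injury or after sham surgery. The animals carried the G93A mutation of SOD1 (superoxide dismutase 1, an antioxidant enzyme), as used in rat models of amyotrophic lateral sclerosis, or were wild-type littermates. Cords were taken 30 min, 4 h, 24 h and 7 days after injury, and 30 min and 4 h after sham surgery. RNA of the rats of each condition was combined into 1 pool, which gave 12 pools on 12 Illumina rat arrays, 6 of each genotype. How many rats entered a pool is not given in the sources used here. Each condition is therefore a single pool with no replicate of its own. The p-values below measure only the spread between these pools, which may be technical.

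The arrays held 22226 probes, of which 13793 were tested because they were detected on at least 2 arrays. The share of probes detected ranged from 49.6% to 53.8% in 11 pools and was 41.3% in the wild-type pool taken 30 min after injury. That pool also stood apart in its levels. Between the genotypes, 1069 probes differed at least 2-fold at 30 min after injury, against 6 to 116 probes in the other 5 pairs of pools. The number of arrays limits the precision of every value.

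Gene names below rest on a re-pairing of probe identifiers with values. As deposited, 1271 probes of olfactory and vomeronasal receptors were detected on 51.8% of arrays on average, and 114 probes of ribosomal and proteasome genes on 53.3%. With the identifiers put in sorted order beside the same values, these shares became 6.08% and 90.7%. The median correlation between 2 probes of one gene moved from -0.07 over 28 genes to 0.74 over 31 genes, across the 12 arrays and with genes not being independent replicates. Sorted identifiers were used throughout, a choice made after the data were seen. Counts of probes do not depend on it, whereas all gene names and gene lists do.

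**Figure D1:**
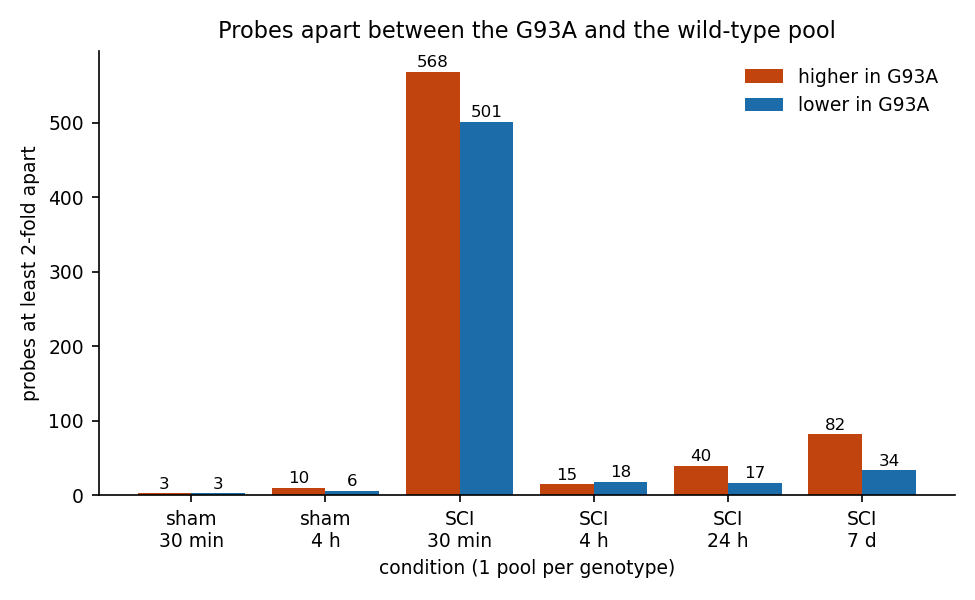
Number of probes (y axis) at least 2-fold higher or lower in the G93A pool than in the wild-type pool, for each of the 6 conditions (x axis, 1 pool per genotype). The pair taken 30 min after injury had 568 probes higher and 501 lower, and the other pairs had at most 82 higher and 34 lower.

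Sham surgery came first, as the background for the injury comparisons. Between 30 min and 4 h after sham surgery, 7 probes rose and none fell. Lcn2 (lipocalin 2, an iron-siderophore binding protein made in inflammation) rose by 2.94 ± 0.31 on the log2 scale (SE, 2 pools against 2, adjusted p = 0.00563). Timp1, an inhibitor of matrix metalloproteinases, rose by 2.85 ± 0.22 (adjusted p = 0.000699). The chemokines Ccl2 (2.72 ± 0.36, adjusted p = 0.0271) and Cxcl11 (2.59 ± 0.37, adjusted p = 0.0455) rose as well, as did Upp1 (2.15 ± 0.27), Sbno2 (1.68 ± 0.20) and the metallothionein Mt1 (1.58 ± 0.13, adjusted p = 0.000785).

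Among the gene lists, cytokines and chemokines rose with sham time (19 genes, 2 up over all probes and 7 adjusted over the list alone; adjusted p = 1.16e-16, and adjusted p = 0.162 with an estimated correlation). Reactive astrocyte genes rose too (15 genes, 2 up over all probes and 5 adjusted over the list alone; adjusted p = 3.54e-17, and adjusted p = 0.055 with an estimated correlation). NF-kB and STAT3 targets rose as a list (adjusted p = 1.44e-15, and adjusted p = 0.0925 with an estimated correlation), with 0 of 14 members past the threshold over all probes and 8 adjusted over the list alone. The skeletal muscle list was higher at 4 h (adjusted p = 0.000188, and adjusted p = 0.563 with an estimated correlation), a call lost without the wild-type 4 h sham pool (adjusted p = 0.885) or the wild-type 30 min sham pool (adjusted p = 0.244). Its median was 0.45 higher in wild-type and -0.06 in G93A pools. Of the other 8 lists called, apoptosis, interferon, cholesterol and oxidative stress genes were higher (adjusted p from 2.02e-08 to 0.000187, and adjusted p from 0.107 to 0.284 with an estimated correlation). Lymphocyte and motor neuron genes were also higher and microglia and glucocorticoid response genes lower, and these 4 calls were each lost without the wild-type 30 min sham pool (adjusted p = 0.0745, 0.0612, 0.131 and 0.518), and each without at least 1 other sham pool as well. With an estimated correlation none of these 4 was called (adjusted p = 0.563, 0.495, 0.517 and 0.324).

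The count of 7 probes became 2 without either 30 min sham pool, 4 without the wild-type 4 h sham pool or either 7 d injury pool, and 27 without either 30 min injury pool. Values without background correction gave 8 higher and 3 lower, and deposited series matrix values 1 higher and 2 lower.

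Injury was compared with the sham pool of the same time at 30 min. Within 30 min, 19 probes rose and none fell, in both genotypes alike in direction. They were led by messages of inflammatory mediators. The chemokine Ccl3 rose by 3.18 ± 0.36 (9.07-fold, SE, 2 pools against 2, adjusted p = 0.0058), the cytokine Il1b by 2.61 ± 0.32 (adjusted p = 0.00659) and the chemokine Ccl4 by 2.51 ± 0.30 (adjusted p = 0.0061). Cxcl1 (2.41 ± 0.35) and Cxcl2 (2.20 ± 0.31), which attract neutrophils, rose as well. The stress-induced transcription factor Atf3 rose by 2.50 ± 0.33 (adjusted p = 0.0113). Fos (2.31 ± 0.25, adjusted p = 0.00539) and Junb (2.27 ± 0.21, adjusted p = 0.00298), subunits of the AP-1 transcription factor, rose with the early response genes Ier2 (2.46 ± 0.31) and Ier3 (2.22 ± 0.27).

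As a list, immediate early genes rose at 30 min, with 7 of 22 measured members up over all probes and 14 adjusted over the list alone (adjusted p = 2.33e-26, and adjusted p = 0.107 with an estimated correlation). The list's median was 1.09 above the own sham pool in each genotype. Cytokines and chemokines rose as well, with 6 of 19 members up on both counts (adjusted p = 3.36e-09, and adjusted p = 0.284 with an estimated correlation). Homeostatic astrocyte genes fell as a list (adjusted p = 0.000943, and adjusted p = 0.385 with an estimated correlation), with 0 of 12 members past the threshold over all probes and 1 adjusted over the list alone. Among them, Slc4a4 was at -1.03 ± 0.37 and Mlc1 at -0.61 ± 0.39, both with adjusted p = 0.625. The list's median was -0.68 in wild-type and -0.08 in G93A pools.

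Complement genes were higher as a list (adjusted p = 0.000711, and adjusted p = 0.324 with an estimated correlation), a call lost without the G93A 30 min injury pool (adjusted p = 0.0616). NF-kB and STAT3 targets were higher (adjusted p = 0.00423, and adjusted p = 0.369 with an estimated correlation), also not without that pool (adjusted p = 0.195). Skeletal muscle genes, markers of tissue around the cord, were higher (adjusted p = 4.95e-06, and adjusted p = 0.506 with an estimated correlation), but not without the wild-type 30 min injury pool (adjusted p = 0.127). All 14 of them lay above the sham pool in wild-type rats, with a median of 0.71, against a median of 0.07 in G93A rats. The other 7 of the 13 lists called at this time were ependymal, interferon, erythrocyte and phagocytic macrophage genes, which were higher, and neuron, glutamate handling and oxidative phosphorylation genes, which were lower. Their adjusted p lay between 0.0205 and 0.043, and their adjusted p with an estimated correlation between 0.34 and 0.666. Each of the 7 was lost without at least 1 of the 4 pools compared, with adjusted p up to 0.572.

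The 30 min count rests on single pools. It was 0 without the wild-type 30 min sham pool (231 probes at an unadjusted p under 0.05 in limma) or without the G93A 30 min sham pool (633 such probes). It was 34 without the wild-type 30 min injury pool, all 19 probes among them, and 4211 without the G93A 30 min injury pool, which leaves the deviating wild-type pool alone to stand for injury. Deposited series matrix values called 3 probes, 0 of them shared, eBayes without a trend called 6, and without background correction 8 rose and 6 fell.

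At 4 h after injury, 72 probes rose and 4 fell against the 4 h sham pools. Ccl3 (3.08 ± 0.36, adjusted p = 0.00519), Il1b (2.52 ± 0.32, adjusted p = 0.00655), Ccl4 (2.50 ± 0.30) and Cxcl1 (2.13 ± 0.35) were again among the largest increases. Fosl1, another AP-1 subunit, rose by 2.79 ± 0.37 (6.94-fold, adjusted p = 0.00933), and Atf3 by 2.02 ± 0.33. Gpx2, a glutathione peroxidase, rose by 2.41 ± 0.29, the TWEAK receptor Tnfrsf12a by 2.25 ± 0.30, Plet1 by 2.21 ± 0.24 (adjusted p = 0.00479) and the serine protease inhibitor Tfpi2 by 1.99 ± 0.30. Slco1c1, a thyroid hormone transporter of the blood-brain barrier, fell by 1.63 on the log2 scale (SE 0.23, adjusted p = 0.0137). Cldn5, the tight junction protein of brain endothelium, fell by 1.27 (SE 0.24, adjusted p = 0.0478), and Txnip, an inhibitor of thioredoxin, fell by 1.01 (SE 0.18, adjusted p = 0.0397).

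Immediate early genes rose as a list at 4 h, with 6 of 22 members up over all probes and 19 adjusted over the list alone (adjusted p = 1.56e-29, and adjusted p = 0.107 with an estimated correlation). Cytokines and chemokines rose (7 of 19 up over all probes; 15 up and 1 down adjusted over the list alone; adjusted p = 1.44e-23, and adjusted p = 0.107 with an estimated correlation). NF-kB and STAT3 targets and adhesion molecules rose (4 of 14 up, 12 adjusted over the list alone; adjusted p = 2.1e-22, and adjusted p = 0.055 with an estimated correlation), among them the endothelial selectins Sele (0.89 ± 0.15) and Selp (0.81 ± 0.14) and the apoptosis inhibitor Birc3 (0.85 ± 0.09). Reactive astrocyte genes rose (5 of 15 up, 10 adjusted over the list alone; adjusted p = 1.44e-15, and adjusted p = 0.055 with an estimated correlation), with Lcn2 at 1.84 ± 0.31, Sphk1 at 1.78 ± 0.25 and Cd44 at 1.09 ± 0.20, each past the threshold. These last 3 lists had also risen with time after sham surgery.

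Apoptosis and p53 targets rose at 4 h (2 of 14 up, 5 adjusted over the list alone; adjusted p = 2.22e-08, and adjusted p = 0.207 with an estimated correlation), led by Tnfrsf12a and the p53 regulator Mdm2 (1.63 ± 0.19). Of the remaining 11 lists called, 10 were higher, with adjusted p from 6.76e-05 for the interferon response to 0.0373 for phagocytic macrophage genes and adjusted p of 0.122 to 0.541 with an estimated correlation. Skeletal muscle was lower (adjusted p = 0.00807, and adjusted p = 0.679 with an estimated correlation), a call lost without the wild-type 4 h injury pool (adjusted p = 0.897) or the wild-type 4 h sham pool (adjusted p = 0.938). Of the 10 higher lists, 5 were not called without the wild-type 4 h sham pool, namely unfolded protein response (adjusted p = 0.136), oxidative stress (adjusted p = 0.0863), phagocytic macrophage (adjusted p = 0.161), antigen presentation (adjusted p = 0.262) and erythrocyte genes (adjusted p = 0.25). Each of these 5 was also lost without 1 of the 4 h injury pools, and the neutrophil list without the G93A one (adjusted p = 0.547).

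The count at 4 h moved from 76 to 0 without the wild-type 4 h sham pool (433 probes at an unadjusted p under 0.05 in limma), to 13 without the G93A 4 h injury pool and to 20 without the G93A 4 h sham pool. It was 22 and 23 without the wild-type and the G93A 30 min sham pool, 34 without either 7 d pool, 47 and 46 without the wild-type and the G93A 24 h pool, and 236 and 233 without the wild-type and the G93A 30 min injury pool. Cldn5 and Txnip lost their calls without most single pools, and their adjusted p then reached 0.49 and 0.409. Deposited series matrix values called 20 probes, eBayes without a trend 14, and values without background correction 39, with 30 higher and 9 lower.

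After 24 h the response was broad, with 1580 probes higher and 1291 lower than the mean of the 4 sham pools. No sham pool was taken at this time, so that time since surgery differs between the groups. Lcn2 rose by 4.08 ± 0.26 (SE, 2 pools against 4, adjusted p = 2.47e-05). Timp1 (3.16 ± 0.19), Gpx2 (3.68 ± 0.25), the protease inhibitor Slpi (3.64 ± 0.33), the calcium binding protein S100a11 (9.19-fold, adjusted p = 4.34e-05) and Gldn (3.16 ± 0.24) followed. Lcn2 and Timp1 had also risen with time after sham surgery. Their mean log2 levels were 12.5 and 13.4 at 24 h after injury, 9.90 and 11.7 in the 4 h sham pools and 6.96 and 8.83 in the 30 min sham pools. The macrophage lysosomal protein Cd68 (3.06 ± 0.23, adjusted p = 4.31e-05), heme oxygenase Hmox1 (2.89 ± 0.21), the Fc receptor Fcgr3a (2.88 ± 0.21) and the interferon-induced Mx2 (2.84 ± 0.23) rose as well.

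Among the 10 largest named decreases at 24 h, Mbp, Thy1 and Gjb6 are on the myelin, neuron and homeostatic astrocyte lists. Myelin basic protein, Mbp, fell by 2.70 (SE 0.24, adjusted p = 9.29e-05). The astrocyte gap junction gene Gjb6 fell by 2.60 (SE 0.29, adjusted p = 0.000292), and Vamp1 (-2.54 ± 0.35, adjusted p = 0.000935) and Thy1 (-2.48 ± 0.35, adjusted p = 0.00111) fell too. Vsnl1 (-2.66 ± 0.55, adjusted p = 0.00764), Map1b (-2.50 ± 0.55), Slc24a2 (-2.39 ± 0.51), Gprc5b (-2.41 ± 0.21), Ppp1r1b (-2.33 ± 0.18) and Tspan7 (-2.30 ± 0.43) completed the 10 largest named decreases. Without the wild-type 24 h injury pool, Vsnl1, Map1b, Slc24a2 and Tspan7 missed the threshold, with adjusted p = 0.126, 0.13, 0.118 and 0.0851. Without the G93A 24 h injury pool the first 3 of these missed it, with adjusted p = 0.0556, 0.0772 and 0.0805.

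Cell cycle genes rose as a list at 24 h, with 16 of 18 members up on both counts, over all probes and adjusted over the list alone (adjusted p = 1.16e-12, and adjusted p = 0.17 with an estimated correlation). Examples were the replication helicase subunit Mcm6 (2.35 ± 0.19), the mitotic kinase Cdk1 (1.93 ± 0.22) and cyclin D1, Ccnd1 (1.58 ± 0.21). Reactive astrocyte genes rose (13 of 15 up on both counts; adjusted p = 2e-12, and adjusted p = 0.055 with an estimated correlation), including Serpina3n (2.84 ± 0.14) and Cd14 (2.56 ± 0.22). Antigen presentation rose (9 of 13 up, 10 adjusted over the list alone; adjusted p = 9.63e-07, and adjusted p = 0.278 with an estimated correlation), with the immunoproteasome subunit Psmb8 at 2.28 ± 0.27. Complement rose (9 of 12 up, 11 adjusted over the list alone; adjusted p = 1.36e-06, and adjusted p = 0.207 with an estimated correlation), as did the interferon response (9 of 15 up on both counts; adjusted p = 2.54e-05, and adjusted p = 0.284 with an estimated correlation).

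Lists of phagocyte and neutrophil genes rose as well at 24 h, of which the first are also expressed by resident microglia. Phagocytic macrophage and lysosome genes had 9 of 19 members up (11 up and 1 down adjusted over the list alone; adjusted p = 5.9e-05, and adjusted p = 0.17 with an estimated correlation). Neutrophil genes had 7 of 13 members up (8 adjusted over the list alone; adjusted p = 0.000455, and adjusted p = 0.324 with an estimated correlation), with S100a8 at 2.37 ± 0.48 and the decoy receptor Il1r2 at 2.14 ± 0.32. Oligodendrocyte and myelin genes fell (10 of 14 down, 12 adjusted over the list alone; adjusted p = 1.18e-06, and adjusted p = 0.107 with an estimated correlation). Neuron genes fell (12 of 20 down, 15 adjusted over the list alone; adjusted p = 4.95e-06, and adjusted p = 0.385 with an estimated correlation), and so did homeostatic astrocyte genes (8 of 12 down, 10 adjusted over the list alone; adjusted p = 5.26e-06, and adjusted p = 0.284 with an estimated correlation). Axon injury genes were higher (8 of 16 up and 2 down; adjusted p = 0.00403, and adjusted p = 0.188 with an estimated correlation), with the neuropeptide precursor Vgf at 2.63 ± 0.24.

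Apoptosis and p53 targets rose too (7 of 14 up, 9 adjusted over the list alone; adjusted p = 9.13e-06, and adjusted p = 0.294 with an estimated correlation), and oxidative phosphorylation genes were lower (3 of 19 down; adjusted p = 0.00403, and adjusted p = 0.541 with an estimated correlation). Glutamate handling genes were lower (4 of 13 down; adjusted p = 0.0241, and adjusted p = 0.401 with an estimated correlation), but not without the G93A 24 h pool (adjusted p = 0.0661). Immediate early genes were higher (6 of 22 up; adjusted p = 0.043, and adjusted p = 0.676 with an estimated correlation), but not without the wild-type 24 h pool (adjusted p = 0.194) or any of 4 other pools, among them the wild-type 4 h sham pool (adjusted p = 0.0863).

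The 24 h count of 2871 fell to 472 without the wild-type and to 1172 without the G93A 24 h pool. It was 1548, 1431 and 1722 without the wild-type 30 min, wild-type 4 h and G93A 30 min sham pool, and 5060 or 5053 without the wild-type or the G93A 30 min injury pool. Against the 4 h sham pools alone 1534 probes were called, and with deposited series matrix values 1498. Median scaling in place of quantile normalization gave 1906 higher and 831 lower.

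By 7 days, 1568 probes were higher and 1329 lower than the mean of the 4 sham pools, again without a sham pool of that time. The 10 largest named increases included genes of phagocytes, the interferon response, complement and matrix. Cd68 rose by 5.25 ± 0.23 (38.0-fold, SE, 2 pools against 4, adjusted p = 5.78e-07) and Fcrl2, an Fc receptor-like gene, by 4.57 ± 0.20 (adjusted p = 5.78e-07). Ncf1, a subunit of the phagocyte NADPH oxidase, rose by 3.62 ± 0.18, the complement subunit C1qc by 3.50 ± 0.18 (adjusted p = 1.41e-06), the chemokine Cxcl13 by 3.38 ± 0.27 and the interferon-induced genes Ifitm1 and Mx1 by 3.55 ± 0.20 and 3.24 ± 0.28. The matrix genes Postn (3.38 ± 0.39, adjusted p = 0.000184) and Col1a1 (3.35 ± 0.41) and the immune receptor gene Ceacam4 (3.48 ± 0.39) rose with them.

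Tnnc2, a troponin of fast skeletal muscle, showed the largest named decrease at 7 d (-2.90 ± 0.23, adjusted p = 2.08e-05). It belongs to the skeletal muscle list, which as a whole was not called at this time. Of the other large decreases, Thy1 is on the neuron list and Nefh on the motor neuron list. Thy1 fell by 2.65 (SE 0.35, adjusted p = 0.000531) and Vamp1 by 2.55 (SE 0.35, adjusted p = 0.000667). Vsnl1 (-2.84 ± 0.55), Scn1a, a sodium channel (-2.46 ± 0.42), Map1b (-2.38 ± 0.55), Pkm (-2.35 ± 0.45), neurofilament heavy chain Nefh (-2.32 ± 0.52), Nat8l (-2.28 ± 0.39) and Nsf (-2.20 ± 0.59, adjusted p = 0.0229) fell as well. Each of these 7 lost its call without the wild-type 7 d pool, with adjusted p from 0.0795 for Nat8l to 0.28 for Nsf. Map1b and Nsf also missed the threshold without the G93A 7 d pool (adjusted p = 0.057 and 0.0886), and Nsf without 3 of the 4 sham pools (adjusted p = 0.067, 0.0811 and 0.053 without the wild-type 30 min, wild-type 4 h and G93A 30 min pool).

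Complement rose as a list at 7 d, with 11 of 12 members up on both counts (adjusted p = 9.42e-13, and adjusted p = 0.107 with an estimated correlation) and examples in Cfd (3.10 ± 0.21), C2 (2.98 ± 0.22) and C4b (2.71 ± 0.24). Phagocytic macrophage and lysosome genes rose (13 of 19 up on both counts; adjusted p = 1.56e-10, and adjusted p = 0.0925 with an estimated correlation), with the adaptor Tyrobp at 2.87 ± 0.26. Homeostatic microglia genes rose (10 of 11 up on both counts; adjusted p = 2.24e-09, and adjusted p = 0.159 with an estimated correlation), with the receptor Trem2 at 3.11 ± 0.19 and Aif1 at 1.94 ± 0.15. Tmem119, the remaining member, was at -0.04 (adjusted p = 0.277). Antigen presentation (11 of 13 up, 12 adjusted over the list alone; adjusted p = 2.24e-09, and adjusted p = 0.194 with an estimated correlation) and fibroblast and matrix genes (13 of 17 up and 1 down on both counts; adjusted p = 3.3e-08, and adjusted p = 0.284 with an estimated correlation) rose too. Cell cycle genes still stood above sham (15 of 18 up, 16 adjusted over the list alone; adjusted p = 2.24e-09, and adjusted p = 0.226 with an estimated correlation).

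Cholesterol synthesis genes fell at 7 d, with 13 of 16 members down and 14 adjusted over the list alone (adjusted p = 3.81e-09, and adjusted p = 0.055 with an estimated correlation). They included Insig1, a regulator of sterol sensing (-1.91 ± 0.40), Idi1 (-1.75 ± 0.21), the squalene synthase Fdft1 (-1.71 ± 0.21) and Msmo1 (-1.61 ± 0.21). Neuron genes fell (16 of 20 down on both counts; adjusted p = 2.98e-08, and adjusted p = 0.324 with an estimated correlation), with Snap25 at -2.19 ± 0.23 and the glutamate receptor subunit Grin1 at -2.03 ± 0.31. Oxidative phosphorylation genes fell (14 of 19 down, 16 adjusted over the list alone; adjusted p = 6.31e-07, and adjusted p = 0.324 with an estimated correlation). Oligodendrocyte and myelin genes fell (5 of 14 down, 7 adjusted over the list alone; adjusted p = 0.00158, and adjusted p = 0.226 with an estimated correlation), with Mbp at -2.10 ± 0.24. The motor neuron list was lower (5 of 14 down and 1 up; adjusted p = 0.0198, and adjusted p = 0.462 with an estimated correlation), and its call was lost without the wild-type 7 d pool (adjusted p = 0.119).

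Reactive astrocyte genes were still higher at 7 d (10 of 15 up, 11 adjusted over the list alone; adjusted p = 1.08e-06, and adjusted p = 0.107 with an estimated correlation). Interferon (8 of 15 up; adjusted p = 0.000124, and adjusted p = 0.318 with an estimated correlation), apoptosis (8 of 14 up; adjusted p = 0.00264, and adjusted p = 0.418 with an estimated correlation) and lymphocyte genes (5 of 13 up; adjusted p = 0.00373, and adjusted p = 0.537 with an estimated correlation) were higher as well. Glucocorticoid response, glutamate handling, proteasome and homeostatic astrocyte genes were lower (adjusted p from 0.0209 to 0.038, and adjusted p from 0.282 to 0.563 with an estimated correlation). Of these 4 calls, the glucocorticoid call was lost without the G93A 7 d pool (adjusted p = 0.101), and the other 3 without the wild-type 7 d pool (adjusted p = 0.0713, 0.0608 and 0.0608). The proteasome and astrocyte calls were also lost without some of the other pools compared, with adjusted p up to 0.0829.

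The 7 d count of 2897 fell to 641 without the wild-type and to 1774 without the G93A 7 d pool. It was 1821, 1649 and 1875 without the wild-type 30 min, wild-type 4 h and G93A 30 min sham pool, and 4916 or 4894 without the wild-type or the G93A 30 min injury pool. Against the 4 h sham pools alone 1905 probes were called, and with deposited series matrix values 1644. Median scaling turned the split to 1092 higher and 1599 lower.

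**Figure D2:**
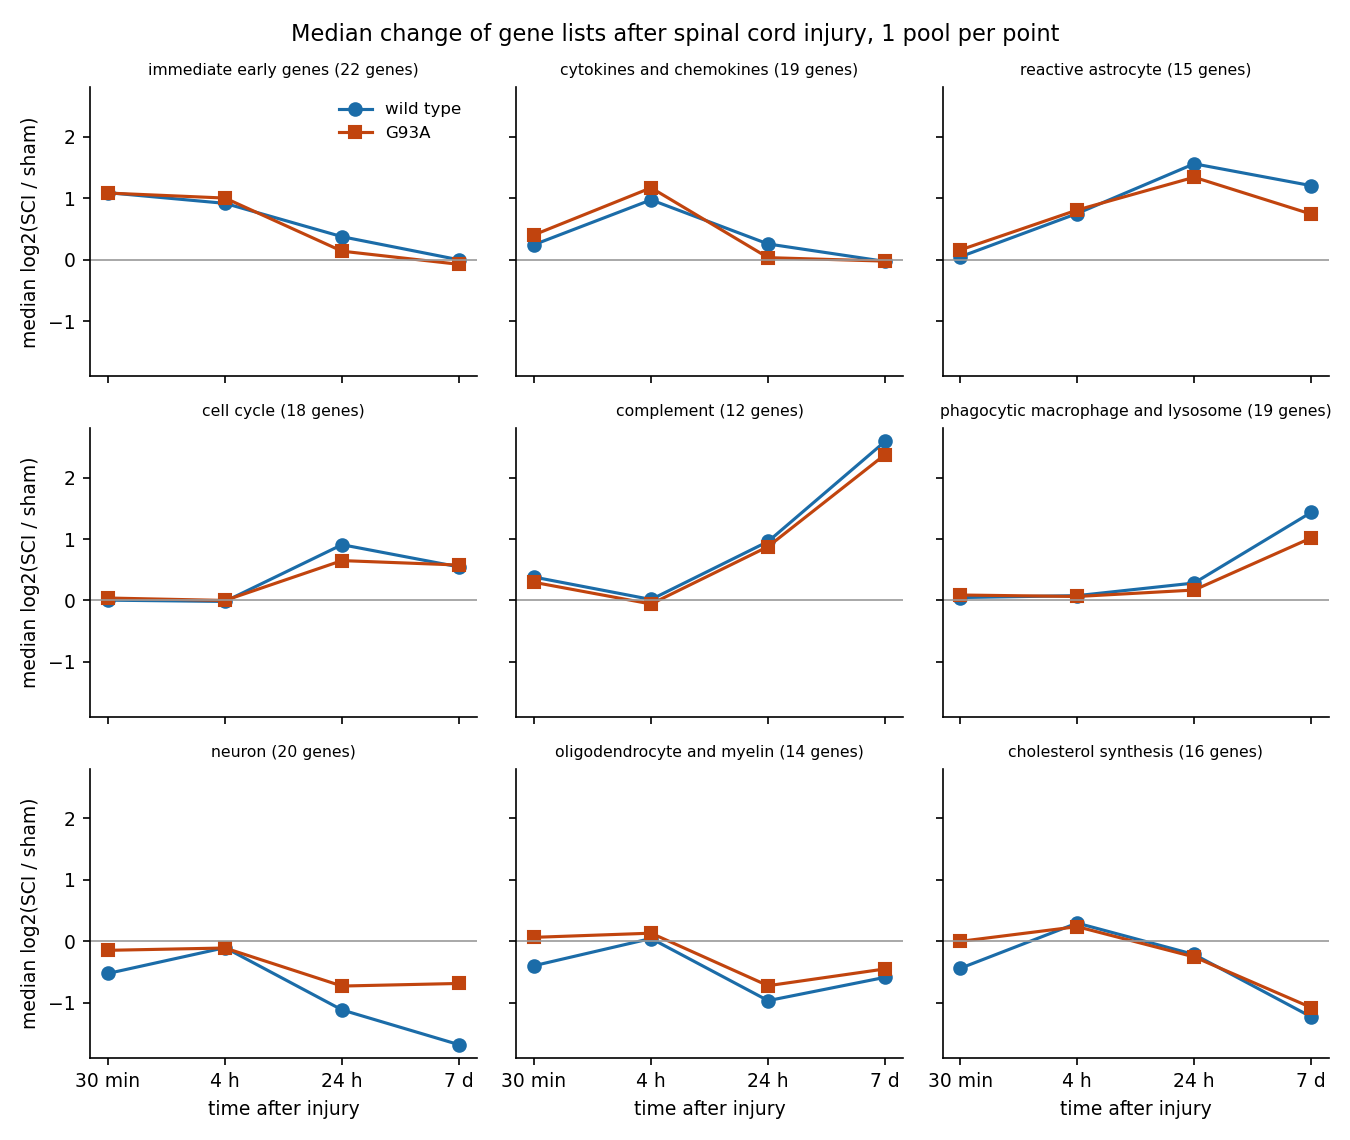
Median log2 difference between the injured pool and its sham (y axis) at 30 min, 4 h, 24 h and 7 d after injury (x axis) for 9 gene lists, with 1 pool per point and no error bar. Blue circles are wild-type and red squares G93A pools; the sham pool of the same time is the reference at 30 min and 4 h, and the mean of the genotype's 2 sham pools later. Immediate early genes stood 1.09 above sham at 30 min in both genotypes, and complement reached 2.59 in wild-type and 2.38 in G93A pools at 7 d.

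The main question of the series was how G93A and wild-type cords differ. No probe was called for genotype over the 6 pairs of pools (limma, 0 of 13793 past the threshold, smallest adjusted p = 0.979, 315 probes at an unadjusted p under 0.05 where chance gives 690). The residual holds the change of the genotype difference between conditions, with the deviating 30 min injury pair among them. A count of 0 therefore does not show that the genotypes are alike. Without that pair, limma gave 453 probes at an unadjusted p under 0.05 and again 0 calls. The Sod1 probe, made for the rat gene, was at -0.05 ± 0.10 (G93A minus wild type, SE, 6 pairs, adjusted p = 0.979), with pairs between -0.27 and 0.35. Rats of this kind carry a mutant human transgene, which a rat probe need not detect, so that this value does not check the genotype labels. Sod1 did not pass the threshold in any injury or sham comparison either, with -0.37 ± 0.14 at 7 d (adjusted p = 0.0951). This became a call without the G93A 7 d pool (adjusted p = 0.0406) or without the wild-type or the G93A 30 min injury pool (adjusted p = 0.0425 and 0.0434).

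The 5 genes with the smallest p for genotype, all with adjusted p = 0.979, were Pacsin1 (0.55 ± 0.13), a synaptic vesicle endocytosis protein, Cyp46a1 (0.07 ± 0.02), the neuronal cholesterol hydroxylase, Olig3 (0.07 ± 0.02), the glial glutamate transporter Slc1a2 (0.48 ± 0.13) and Ppp2r5b (0.70 ± 0.19). The first 4 lay above 0 in 6 of 6 pairs. Of these, Cyp46a1 and Olig3 were near background, detected on 2 and 3 of 6 wild-type arrays, with pair differences of at most 0.11 and 0.10. Simulated genotype differences of 1 on the log2 scale were recovered in 94.0% of cases and differences of 0.5 in 56.0%. The simulation held the same 13793 probes, with noise independent between probes and pools and 50 randomly drawn probes changed at each size at once. A change in fewer probes faces a stricter adjusted threshold, and no simulated pool deviated. These shares are therefore no estimate of power in the real pools.

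Homeostatic astrocyte genes were higher in G93A pools as a list (12 genes, median 0.34, 11 above 0, and median 0.19 without the wild-type 30 min injury pool), with 0 members past the threshold over all probes and 2 adjusted over the list alone, Slc1a2 and the sodium pump subunit Atp1b2 (0.37 ± 0.10). The adjusted p was 3.84e-08, and adjusted p = 0.207 with an estimated correlation. Its mean was above 0 in 6 of 6 pairs (0.28, exact sign-flip permutation test over 64 flips, two-sided p = 0.0312, the smallest possible, and 0.578 adjusted over 37 lists). Neuron genes were higher (20 genes, 17 above 0, 0 members past the threshold, adjusted p = 0.000249, and adjusted p = 0.503 with an estimated correlation). Glutamate receptor and handling genes were higher too (adjusted p = 0.00614, and adjusted p = 0.34 with an estimated correlation). This list shares members with the astrocyte list, such as Slc1a2, and with the neuron list, such as Grin1, and is no independent result. The means of the neuron and glutamate lists were above 0 in only 4 and 5 of 6 pairs (exact sign-flip permutation test, unadjusted p = 0.25 and 0.0625). Interferon response genes were lower (adjusted p = 0.00358, and adjusted p = 0.385 with an estimated correlation), in 6 of 6 pairs. These 3 calls were lost without the 7 d pair or either of its pools (adjusted p = 0.103 to 0.15).

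Lymphocyte genes were lower in G93A pools (13 genes, median -0.04; adjusted p = 0.000129, and adjusted p = 0.402 with an estimated correlation). Skeletal muscle genes were lower too (adjusted p = 9.4e-06, and adjusted p = 0.517 with an estimated correlation), with a median difference of -0.39 in the 4 h sham pair and -0.74 in the 30 min injury pair and between -0.04 and 0.11 in the other 4 pairs. Without the wild-type 30 min injury pool 7 lists were called for genotype, and the skeletal muscle list, genotype comparison, kept its call (adjusted p = 0.0356 over all pairs of list and contrast). Its median difference, however, moved from -0.15 to -0.08. Adjusted over the 37 lists of this comparison alone, the skeletal muscle list was at adjusted p = 0.0585 and homeostatic astrocyte genes at adjusted p = 2.12e-06, both with adjusted p = 0.845 with an estimated correlation. In the test of list means, 2 of 37 lists had an unadjusted p under 0.05 by the exact sign-flip permutation test and none after adjustment. Genes of other amyotrophic lateral sclerosis loci showed no call as a list (12 genes, adjusted p = 0.719).

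Whether the genotype difference changed with injury was tested as an interaction, 4 injured pairs against 2 sham pairs. No probe passed (limma, smallest adjusted p = 0.948, 344 probes at an unadjusted p under 0.05). The 5 genes with the smallest p, all with adjusted p = 0.948, were Dpp3 (-0.91 ± 0.23), Krt72 (-0.15 ± 0.04), Magee1 (0.86 ± 0.24), Pcdh9 (1.01 ± 0.28) and Tnfrsf11b (1.22 ± 0.35), whose 4 injured pairs all lay on one side of both sham pairs. Leaving out the G93A 30 min sham pool gave 3 calls and every other single pool 0.

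Lists called for the interaction were lymphocyte (lower in injured G93A pairs, adjusted p = 0.000152, and adjusted p = 0.38 with an estimated correlation), neuron (higher, adjusted p = 0.00403, and adjusted p = 0.593 with an estimated correlation) and homeostatic astrocyte genes (higher, adjusted p = 0.0186, and adjusted p = 0.506 with an estimated correlation). No member passed over all probes or adjusted over the list alone. The lymphocyte call was lost without the wild-type or the G93A 4 h sham pool (adjusted p = 0.194 and 0.177), and the neuron call without these (adjusted p = 0.131 and 0.117) or without the wild-type or the G93A 7 d pool (adjusted p = 0.146 and 0.15). The astrocyte call was lost without either pool of 3 pairs, 30 min sham (adjusted p = 0.112 and 0.109), 30 min injury (adjusted p = 0.0917 and 0.102) and 7 d injury (adjusted p = 0.0544 and 0.0551).

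At single times each genotype had 1 pool, so that values have no replicate check and no p. The neuron list's median difference, G93A minus wild type, was 0.12 in the 30 min sham pair, -0.16 in the 4 h sham pair, 0.38 at 30 min, -0.15 at 4 h, 0.33 at 24 h and 0.80 at 7 d after injury, the last with 19 of 20 genes above 0. The 7 d value stood at percentile 100 of 10000 random lists of like expression, as a description of these pools. Relative to its own shams, the list's median at 7 d was -1.69 in wild-type and -0.69 in G93A pools. Across the 13793 probes, the 2 genotypes' responses had a correlation of 0.91 at 24 h and 0.89 at 7 d, with probes not being independent replicates. The slope of the G93A against the wild-type response was fitted by total least squares, the main axis of the scatter, and is not a regression slope. It was 0.80 at 24 h and 0.71 at 7 d, against 1.18 at 4 h and -0.07 at 30 min. The correlation was 0.50 at 4 h and -0.16 at 30 min, so that the slopes at these times are poorly fixed. With median scaling the slope at 4 h was 0.875, so that its side of 1 depends on the normalization. Of the probes called, 2127 of 2871 at 24 h and 2316 of 2897 at 7 d changed more in the wild-type pools with quantile normalization. With median scaling the median ratio of G93A to wild-type response at 24 h was 0.987 for risen and 0.716 for fallen probes. Under that scaling a larger wild-type response is thus hardly seen among probes that rose by 24 h.

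**Figure D3:**
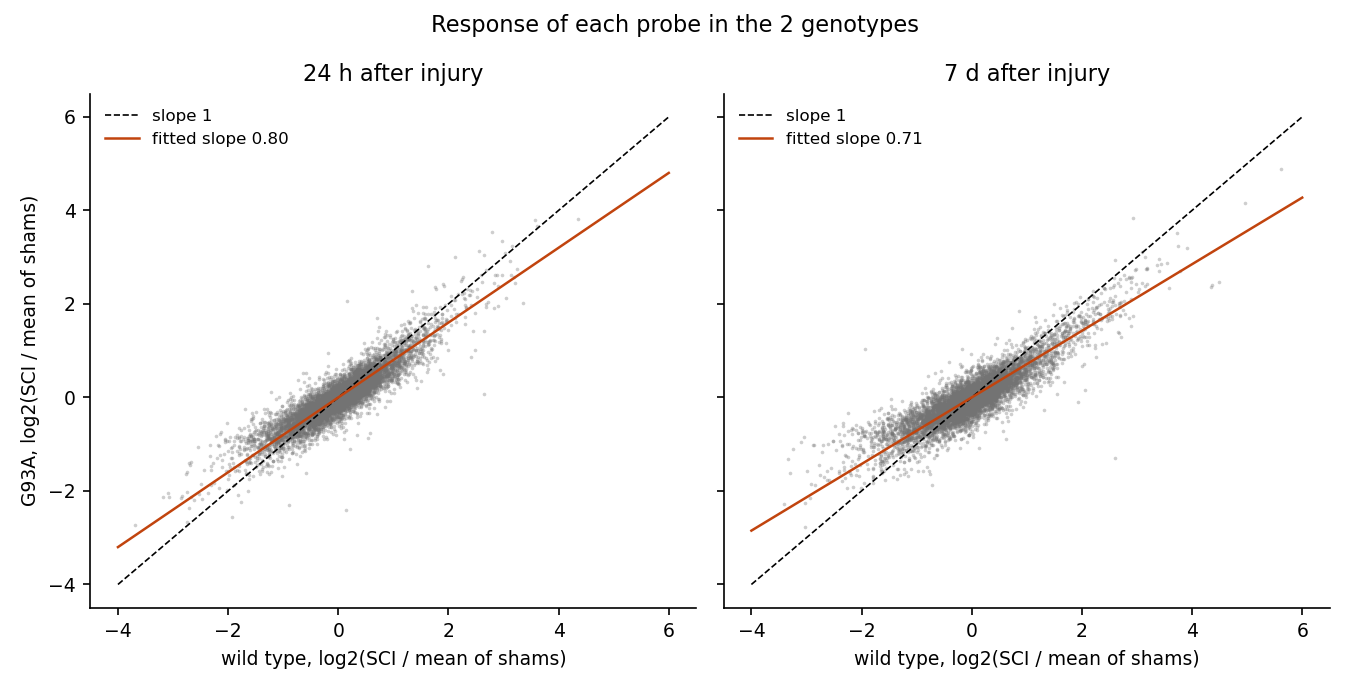
Log2 difference between the injured pool and the mean of the same genotype's 2 sham pools for each of 13793 probes, in wild-type (x axis) and G93A rats (y axis), 24 h (left) and 7 d (right) after injury. The dashed line has slope 1. The red line has the slope fitted by total least squares, 0.80 at 24 h and 0.71 at 7 d, so that points lie on average closer to 0 in G93A than in wild-type pools.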

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

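The tests by gene span, skeletal muscle, condition label, late slopes, tissue ratios and late genotype difference were chosen only after the results were seen, whereas leave-outs, normalization settings and the estimated correlation were fixed beforehand, and how each test would be read was written with the values known.

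The genotype difference of 3 gene lists differed between injured and sham pairs by the interaction term. Neuron genes were higher in injured G93A pairs (20 genes, median 0.42, adjusted p = 0.00403), as were homeostatic astrocyte genes (12 genes, median 0.20, adjusted p = 0.0186). Lymphocyte genes were lower (13 genes, median -0.09, adjusted p = 0.000152). With an estimated correlation the adjusted p was 0.593, 0.506 and 0.38.

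For the neuron list, the wild-type 30 min injury pool alone is argued against, since without that pool the adjusted p was 0.00203. Genes of the list moving together between pools may account for the call, because the adjusted p was 0.593 with the correlation estimated from these pools. That setting also lowers the degrees of freedom, so that the loss cannot be put on correlation alone. A change of the genotype difference with injury stays open as a hypothesis. Leaving out 1 pool acts here nearly as leaving out its pair, so that it cannot point to 1 pool of a pair. The call was lost without the wild-type or the G93A 7 d pool (adjusted p = 0.146 and 0.15) and without the wild-type or the G93A 4 h sham pool (adjusted p = 0.131 and 0.117).

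The wild-type pool taken 30 min after injury stood apart, with 41.3% of probes detected and 1069 probes at least 2-fold from its G93A partner. The choice among the normalizations tried is argued against as the cause, since under each setting its pair had at least 5.12 times as many such probes as any other pair. All settings start from the same deposited signals, so that a technical fault of this array was not tested. Its signals ran from -44.5 to 50117, where the other arrays had none below -22.4 or above 25039. Its series matrix line had the highest slope, 0.42, and the lowest intercept, 0. A label of another surgery or time is argued against too. Immediate early genes lay 1.09 above the wild-type 30 min sham pool, against -0.10 and -0.01 for the 4 h sham pools. The 7 probes that rose with sham time lay 0.75 above it, where every pool taken at 4 h or later lay at least 1.70 above its genotype's 30 min sham pool. For the 4 h sham pools that height follows from how these 7 probes were chosen, so that only the injury pools test it. A swap with the G93A 30 min injury pool was not tested. In that pool immediate early genes also lay 1.09 above its sham pool, and the 7 probes 0.39. Skeletal muscle in the tissue piece cannot be told apart from other causes, with a list median of 0.709, because no value here fixes how much muscle would be needed. Loss of signal from long genes may contribute, since the rank correlation of the genotype difference with gene span was 0.237 in this pair and between -0.12 and 0.092 in the others, across 9315 genes, which are not independent replicates, but gene span is not transcript length and RNA quality was not analysed here.

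The late response was smaller in G93A pools, with slopes of 0.80 at 24 h and 0.71 at 7 d. Normalization is argued against as the whole cause of the overall slope, since the highest slope over the settings was 0.841. For risen probes the size depended on it. With median scaling their median ratio of G93A to wild-type response was 0.987 at 24 h and 0.916 at 7 d, against 0.812 and 0.754 in the fit used above. For fallen probes it was 0.716 at both times with median scaling, against 0.805 and 0.735. Less injured tissue in the G93A pools cannot be told apart, because the median ratios of risen and fallen probes differed by 0.00710 at 24 h and 0.0196 at 7 d in the fit used above but by up to 0.27 over the settings, and with quantile normalization after other background steps the gap was larger too. Variation between single pools also cannot be told apart, since the genotype difference at 24 h and 7 d against the other pairs gave 0 probes in limma, with 565 at an unadjusted p under 0.05 where chance gives 690, and without the wild-type 30 min injury pool 4 probes and 1729. Lists were called with camera in that comparison, with neuron genes higher (adjusted p = 2.44e-07). Skeletal muscle genes, markers of tissue around the cord, were higher too (median 0.26, adjusted p = 0.0224). Without the wild-type 30 min injury pool this list was not called (median 0.07). Its mean genotype difference was -0.09 at 24 h and 0.05 at 7 d after injury. In the 4 h sham and the 30 min injury pair it was -0.57 and -0.63. Among others, cytokine, interferon, cell cycle and fibroblast genes were lower (adjusted p from 5.1e-05 to 0.00113). In that order, their mean genotype differences were -0.49, -0.15, -0.35 and -0.06 at 24 h. At 7 d they were -0.15, -0.47, 0.04 and -0.63, so that each list differed mainly at 1 of these times. Fibroblast genes were also higher in G93A in the 30 min and 4 h injury pairs (0.32 and 0.25), part of the reference. None of the lists of that comparison was called with an estimated correlation (adjusted p of 0.481 or more), so that a milder response in G93A rats remains a hypothesis.

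For the genotype comparison, the real count and the highest of the other swaps of genotype within pairs were 0 probes, so that 32 of 32 reach the real count by necessity and the swaps test nothing. For the interaction, the 15 choices of 4 pairs are too few for a share under 0.05. The real choice gave 0 probes and the highest other 5.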

How the results depend on the processing

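The pairing of identifiers as deposited was added as an alternative after the data were seen, and the other settings were chosen beforehand. Low signal over background limits the dim probes, and the lack of replicate pools limits every count. The genotype and interaction counts were 0 under every other normalization, filter and eBayes setting. The cause of the changes below was not tested unless given.

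Without background correction, 39 probes were called at 4 h and 11 for sham time. With saddle-point background and an offset of 50, which changes both at once, 19 were called for sham time. Median scaling gave 156 at 4 h. Deposited series matrix values gave 3 at 30 min, 20 at 4 h, 1498 at 24 h, 1644 at 7 d and 3 for sham time. Without a filter 4 were called for sham time, and with detection on all 12 arrays 49 at 4 h. Without an eBayes trend 6 were called at 30 min, 14 at 4 h and 4 for sham time. Against the 4 h sham pools alone, a fit with fewer control pools, the counts were 1534 at 24 h and 1905 at 7 d. Of 84 list calls, 0 held with an estimated correlation and 0 with identifiers as deposited.

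Leaving out 1 pool or pair gave 0 to 4211 probes at 30 min, 0 to 236 at 4 h, 472 to 5065 at 24 h, 641 to 4937 at 7 d, 2 to 27 for sham time, 0 for genotype, 0 to 3 for the interaction and 15 to 94 list calls. The lowest list counts come from leaving out a sham pair, after which fewer contrasts can be tested.

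Probes at least 2-fold apart between genotypes numbered, without background correction, 64 and 124 in the 30 min and 4 h sham pairs and 3158, 280, 386 and 545 at 30 min, 4 h, 24 h and 7 d after injury. Series matrix values gave 12, 30, 2098, 60, 90 and 177 in the same order. Saddle-point background with an offset of 50 gave 25 in the 4 h sham pair and 21 at 4 h after injury. Median scaling gave 78, 127 and 219 at 4 h, 24 h and 7 d after injury.

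For 365 values of named genes and list examples, 8353 of 9130 repeats kept direction and side of the threshold, 670 lost a call, 80 gained one and 26 moved. Gria4 at 24 h (-0.13, SE 0.03, adjusted p = 0.0167) became 0 (adjusted p = 1) with series matrix values, where all its values lie at the floor. For the 84 list calls, estimated correlation apart, 1819 of 1994 repeats kept the call, 173 lost it and 2 moved. Camera has no robust setting, so that none was run for lists.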

Other observations

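The comparison of 7 d with 24 h after injury was chosen after the data were seen, as were the genes named from it.

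Between 24 h and 7 d after injury, 408 probes rose and 216 fell. Genes of microglia and macrophages were among the largest increases, with the Fc receptor-like gene Fcrl2 up by 4.07 ± 0.23 on the log2 scale (SE, 2 pools against 2, adjusted p = 1.91e-05) and the receptor Trem2 up by 2.69 ± 0.22 (adjusted p = 0.000106). The complement gene C4b rose by 2.65 ± 0.28 and the collagens Col1a1 and Col3a1 by 2.61 ± 0.47 and 2.56 ± 0.32. The chemokines Ccl2 (-3.65 ± 0.36, adjusted p = 0.000265) and Ccl7 (-3.22 ± 0.30) fell, as did Lcn2 (-2.62 ± 0.31), the neutrophil gene S100a8 (-2.53 ± 0.55, adjusted p = 0.0263) and Serpina3n (-2.51 ± 0.16).

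As lists, adjusted over the 37 lists of this comparison, homeostatic microglia genes rose (11 genes, median 0.91, adjusted p = 2.14e-14, and adjusted p = 0.0699 with an estimated correlation), and so did complement (adjusted p = 3.3e-09, and adjusted p = 0.0749 with an estimated correlation) and fibroblast and matrix genes (adjusted p = 3.76e-09, and adjusted p = 0.155 with an estimated correlation). Cholesterol synthesis genes fell (16 genes, median -0.98, adjusted p = 1.1e-11), the only one of the calls that held with an estimated correlation (adjusted p = 0.0214). Reactive astrocyte genes fell (median -0.53, adjusted p = 3.27e-05, and adjusted p = 0.0749 with an estimated correlation), as did proteasome genes (median -0.39, adjusted p = 6.09e-05, and adjusted p = 0.0749 with an estimated correlation). The same fit holds 1 pool per genotype and time.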
